A study of Mus musculus with 29 samples.

How the data were processed

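RNA of 11 B cell and tumour samples and of 18 fibroblast samples was read as 1 value per gene and library. Per the labels, libraries were made from total RNA after removal of ribosomal RNA, and nascent RNA was labelled with 300 µM 4sU for 10 min. Values are in FPKM per the file headers and were deposited with 1 decimal for B cells and 3 decimals for fibroblasts. The authors aligned reads to mm9, and the tools they name are TopHat2 2.0.8, TopHat, SAMtools and HTSeq 0.5.3p9. The annotation, read filters and the rule behind the scale are not stated. The files hold no counts, and the spacing of the lowest values in each file gives a denominator of 0.826 to 1.47 M reads for the B cell files, 16.97 to 17.1 M for the 16 total RNA fibroblast files and 27.8 and 24.4 M for the 4sU files at 0 and 4 h. With gene lengths from a current annotation, this comes to 8.51 to 15.8 M reads on genes in B cells, so the B cell values lie 10.2 to 11.5 times above FPKM counted over reads on genes. They were not rescaled. Coordinates of the 2 genome builds were not mixed, since only symbols and lengths were used.

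Groups were WT_spleen, Tg_spleen, Tg_lymphnode, OHT_0h, OHT_4h, OHT_8h and OHT_16h, and 4sU_0h and 4sU_4h with 1 library each. Values were taken as log2(FPKM + 0.5) on the deposited scale. Genes with at least 1 FPKM in as many libraries as the smaller group holds were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). Each B cell comparison was fitted on its own 2 groups, and the 16 total RNA fibroblast libraries in 1 fit. P-values are moderated t-tests, two-sided, adjusted by Benjamini-Hochberg over the genes tested, with a call at an adjusted p under 0.05. Fold changes are limma coefficients. Tables and figures used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

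A total of 24 gene lists and 8 marker lists of other cell types were tested with limma camera, two-sided, at the preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were counted as higher or lower with p adjusted over all genes and over the list alone. Of the calls of lists, only that of collagen and extracellular matrix in Tg_lymphnode vs WT_spleen held with an estimated correlation, and not without Tg_lymphnode replicate 3. For 4sU, which has 1 library per time, log2 ratios of FPKM + 0.5 are given with no test, and the median of each list is placed among 10000 random lists of the same size matched on mean level in 20 bins. Overlaps of B cell and fibroblast calls were tested with Fisher's exact test, two-sided. Overlaps of comparisons with a shared control were set beside 6 splits of the controls. In 50 simulations, unchanged groups had a mean of 0.02 to 0.24 calls, too few to judge sharing by, so they are not used.

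The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names Myc and, per comparison, the 6 largest rises and falls (4 for Tg_lymphnode vs Tg_spleen and OHT_16h vs OHT_4h) among called genes whose groups do not overlap and whose mean is at least 5 FPKM in the higher group. It also names up to 3 members per described list with the smallest adjusted p, or the member with the highest level where none is called. For 4sU it names the 6 largest rises and falls with at least 5 FPKM in the higher library and more than 0 in the other. Both rankings leave out, by symbol, predicted and clone-named genes and small RNAs. They also leave out immunoglobulin heavy and light chain genes and T cell receptor genes. Alternatives were a pseudocount of 0.1 or 1, no filter or a filter of 5 FPKM, median ratio scaling, quantile normalization, array weights, limma without trend and robust, the fit of other groups, a replicate block and leaving out each library. Alternatives added after the data were seen were a filter of 10 with a pseudocount of 5, a split or covariate by Rpph1 level, leaving out the fibroblast libraries numbered 4 and OHT_16h replicate 2, genes under 50 FPKM, and list tests without Tg_lymphnode replicate 3. Libraries were not removed from the comparisons for their values.

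The fit was checked on simulated data with the spread of each gene in the real libraries. In them, 100 genes were changed by a log2 of 1 and 100 by a log2 of 2, alternately raised and lowered. The share recovered was 57% and 91% for Tg_spleen vs WT_spleen and 29% and 73% for Tg_lymphnode vs WT_spleen. It was 7% and 46% for Tg_lymphnode vs Tg_spleen and 85% and 97% for OHT_4h vs OHT_0h. Of the unchanged genes, 3, 7, 2 and 6 were called. Fewer genes were changed than were called in each of these real comparisons, which makes the adjusted threshold stricter in the simulation. Noise was drawn for each gene alone, so effects that genes of a library share were left out. These shares and counts therefore hold for the simulated setting and do not give the recovery or false calls in the real data. Correlations of log2 values between replicates were 0.969 to 0.974 in WT_spleen, 0.948 to 0.978 in Tg_spleen, 0.886 to 0.945 in Tg_lymphnode and 0.970 to 0.991 in the fibroblast groups.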

Results

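RNA was sequenced in 29 libraries from mouse cells in which Myc, a transcription factor that drives cell growth, was raised in different ways. Eμ-myc mice carry a Myc transgene under an immunoglobulin enhancer, which is active in B cells. B cells were enriched on B220 beads from spleens of wild-type mice (WT_spleen, n = 4) and of transgenic mice (Tg_spleen, n = 4), all 6 to 8 weeks old. Cell suspensions of tumours were made from lymph nodes of transgenic mice without further purification (Tg_lymphnode, n = 3). The second system was 3T9 mouse fibroblasts carrying MycER, a Myc protein that 4-hydroxytamoxifen activates. Total RNA was taken after 0, 4, 8 and 16 h of 400 nM 4-hydroxytamoxifen (OHT_0h, OHT_4h, OHT_8h and OHT_16h, n = 4 each). Nascent RNA, labelled for 10 min with 300 µM 4-thiouridine (4sU), came from 1 library at 0 h and 1 at 4 h. The B cell files list 21819 genes and the fibroblast files 21675. The files give FPKM and no counts, so the depth of each library is not stated. The median over all listed genes was 11 to 17.3 FPKM in the B cell libraries and 2.11 to 3.96 FPKM in the 16 total RNA fibroblast libraries. The 2 sets lie on different scales, so levels are compared only within a set. Group values are mean FPKM ± SD over the n given here. The largest rises and falls are those among genes that meet the rule for named genes. That rule leaves out predicted genes, small RNAs, and immunoglobulin and T cell receptor genes.

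In spleen B cells, the transgene was compared with wild type to ask which genes change with Myc in spleens of mice 6 to 8 weeks old. Myc itself was at 1556 ± 604 against 226 ± 34.7 FPKM (log2 fold change 2.72, adjusted p = 0.000757). The largest rises were Car12 (40.4 ± 14.8 against 1.02 ± 0.236 FPKM, log2 fold change 4.69, adjusted p = 0.000446), a carbonic anhydrase, and Nav2 (117 ± 70.1 against 3.8 ± 0.455 FPKM, log2 fold change 4.62, adjusted p = 0.000446). They were followed by Eps8l2 (4.58), Ptgr1 (4.57), Uchl1 (4.57), a ubiquitin hydrolase, and Ltbp4 (4.43), with log2 fold changes in parentheses. The largest falls were Klra17 (0.65 ± 0.854 against 14.5 ± 10.7 FPKM, log2 fold change -3.69, adjusted p = 0.00558), a gene of the Ly49 receptor family, and Eya1 (2.33 ± 1.15 against 32.1 ± 5.5 FPKM, log2 fold change -3.62, adjusted p = 0.00109). Then came Crisp3 (-3.11), Spaca1 (-3.09), Cd276 (-2.95) and Steap4 (-2.81). Of 14021 genes tested, 2206 rose and 1712 fell. At least a 2-fold change was seen in 1016 of the rises and 686 of the falls.

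**Figure D1:**
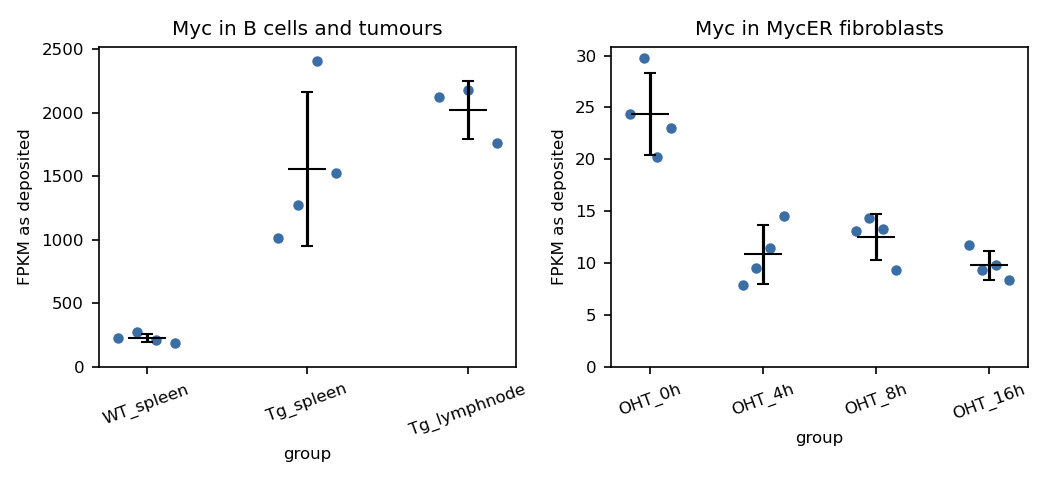
Myc level in FPKM as deposited (y axis, from 0) by group (x axis), for B cells and tumours on the left and MycER fibroblasts on the right, which lie on different scales. Points are libraries, and horizontal marks with bars are the mean and SD (n = 3 or 4). Tg_spleen lay at 1556 ± 604 FPKM against 226 ± 34.7 in WT_spleen, and fibroblasts fell from 24.3 ± 3.98 at 0 h to 9.78 ± 1.41 at 16 h.

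Genes of several growth lists rose in Tg_spleen. For nucleolar ribosome biogenesis, 31 of 37 rose and 0 fell (36 and 0 adjusted over the list alone), among them Dkc1 (849 ± 179 against 286 ± 24.9 FPKM), which modifies ribosomal RNA, and Wdr12 (278 ± 35.1 against 125 ± 6.82 FPKM). Of ribosomal proteins, 20 of 35 rose and 0 fell (26 and 0 adjusted over the list alone), led by Rps2 (927 ± 166 against 466 ± 66 FPKM). Of translation factors, 16 of 22 rose and 0 fell (20 and 0 adjusted over the list alone), and of aminoacyl-tRNA synthetases 16 of 20 rose and 0 fell (17 and 0 adjusted over the list alone). Of nucleotide and one-carbon synthesis, 26 of 28 rose and 0 fell (27 and 0 adjusted over the list alone), with Tyms (113 ± 42.4 against 20.3 ± 2.09 FPKM), thymidylate synthase, and Ctps (368 ± 114 against 123 ± 8.32 FPKM). Of polyamine synthesis, 2 of 6 rose and 0 fell (5 and 0 adjusted over the list alone), with Srm (348 ± 195 against 96.2 ± 13.8 FPKM), spermidine synthase. Of protein folding, 15 of 16 rose and 0 fell (15 and 0 adjusted over the list alone), with Hspd1 (975 ± 342 against 294 ± 33.1 FPKM), a mitochondrial chaperone. Of oxidative phosphorylation, 22 of 28 rose and 0 fell (26 and 0 adjusted over the list alone). Of glycolysis, 9 of 20 rose and 2 fell (9 and 2 adjusted over the list alone), with Slc16a1 (598 ± 364 against 73.5 ± 13.7 FPKM), a lactate transporter. Of cholesterol synthesis, 3 of 15 rose and 0 fell (5 and 0 adjusted over the list alone). Cell division genes had the highest medians. Of DNA replication, 25 of 28 rose and 0 fell (26 and 0 adjusted over the list alone), with Cdc6 (129 ± 63.4 against 16.8 ± 3.17 FPKM), which loads the replicative helicase. Of mitosis, 25 of 26 rose and 0 fell (25 and 0 adjusted over the list alone), with Kif11 (618 ± 343 against 83.3 ± 10.4 FPKM), a spindle motor, and Top2a (2307 ± 1353 against 325 ± 41.4 FPKM), a topoisomerase. The median log2 fold change was 2.42 for mitosis, 2.12 for replication-dependent histones and 1.57 for DNA replication. Of replication-dependent histones, 14 of 15 rose and 0 fell (15 and 0 adjusted over the list alone). Each of these lists was higher by camera (adjusted p = 2.84e-16 to 0.0208), and none passed with an estimated correlation (adjusted p = 0.376 with an estimated correlation for each).

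**Figure D2:**
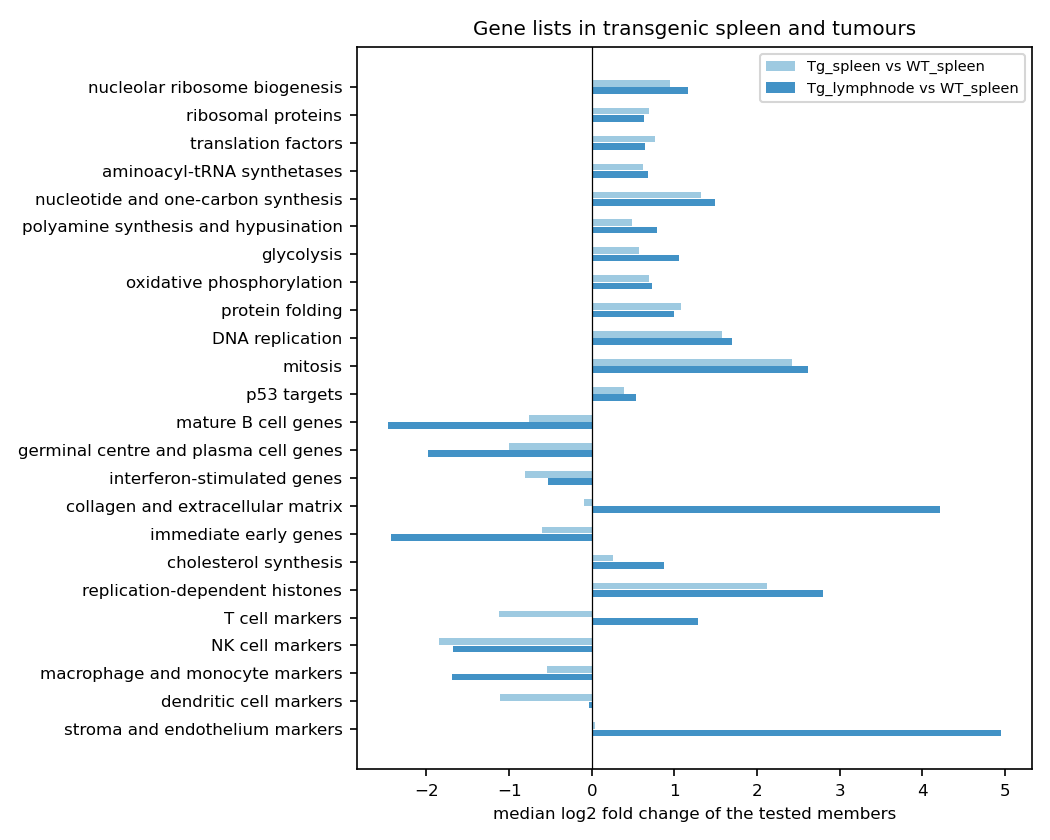
Median log2 fold change of the tested members of each gene list (x axis) for Tg_spleen and Tg_lymphnode against WT_spleen (bars), for lists that passed camera in either comparison (y axis). Mitosis had medians of 2.42 and 2.62, mature B cell genes -0.76 and -2.47, and collagen and extracellular matrix -0.09 and 4.21.

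Genes of mature B cells fell in Tg_spleen. Of that list, 0 of 26 rose and 16 fell (0 and 23 adjusted over the list alone), with Fcer2a (561 ± 272 against 2248 ± 335 FPKM), the low-affinity IgE receptor CD23, and Btla (1479 ± 689 against 3481 ± 314 FPKM). Of germinal centre and plasma cell genes, 0 of 12 rose and 6 fell (0 and 9 adjusted over the list alone), with Bcl6 (44.9 ± 14.7 against 188 ± 27.9 FPKM), a transcriptional repressor that germinal centres need, and Igj (1843 ± 862 against 5603 ± 865 FPKM), the immunoglobulin joining chain. Of interferon-stimulated genes, 0 of 18 rose and 6 fell (0 and 12 adjusted over the list alone), with Stat2 (240.2 ± 49.2 against 367 ± 51.9 FPKM, call lost without Tg_spleen replicate 5 or WT_spleen replicate 1 or 4, adjusted p = 0.0516 to 0.0668). Of p53 targets, 6 of 17 rose and 1 fell (6 and 1 adjusted over the list alone), with Gtse1 (110.4 ± 67.7 against 18.2 ± 2.33 FPKM) and Bbc3 (47.4 ± 10 against 19.6 ± 8.4 FPKM), which encodes Puma. Within the Bcl2 family list, Cdkn2a (17.1 ± 13.7 against 1.77 ± 1.23 FPKM), the Arf locus, rose and Bcl2 (173 ± 96.8 against 440.1 ± 18 FPKM) fell. Rag2 (42 ± 29.8 against 1.8 ± 1.02 FPKM) and Rag1 (281 ± 144 against 28.4 ± 20.7 FPKM), the antigen receptor recombinases, also rose, while Kit (5.85 ± 1.62 against 15.6 ± 4.36 FPKM), a receptor of progenitors, fell. Their list, B cell progenitor genes, did not pass (adjusted p = 0.0859), and 4 of 15 rose and 2 fell (4 and 2 adjusted over the list alone). Camera gave adjusted p = 1.37e-07 for mature B cell genes, 0.00172 for germinal centre genes, 9.22e-05 for interferon-stimulated genes and 0.0318 for p53 targets. With an estimated correlation they did not pass (adjusted p = 0.458 with an estimated correlation for interferon-stimulated genes and 0.376 for the others). Markers of other cells fell too. Of NK cell markers, 0 of 8 rose and 6 fell (0 and 8 adjusted over the list alone), with Nkg7 (16.5 ± 8.84 against 58.1 ± 18.8 FPKM). Of T cell markers, 0 of 13 rose and 2 fell (0 and 8 adjusted over the list alone), and of dendritic cell markers 0 of 6 rose and 3 fell (0 and 5 adjusted over the list alone). Their camera results were adjusted p = 0.000907, 0.00341 and 0.0122, against adjusted p = 0.376, 0.458 and 0.376 with an estimated correlation.

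Within the 2 spleen groups, libraries differed in Rpph1, the RNA of ribonuclease P. WT_spleen replicates 1 and 3 and Tg_spleen replicates 2 and 3 lay between 545353 and 735331 FPKM, and the other 4 between 153474 and 215865 FPKM. With 2 against 2 libraries, limma found 908 higher and 518 lower genes among those with high Rpph1, and 1960 higher and 1374 lower among those with low Rpph1. Myc was higher in both sets (log2 difference 2.19 and 3.24). The median log2 difference was 1.71 and 3.17 for mitosis, 0.95 and 2.15 for DNA replication, 0.76 and 1.15 for nucleolar ribosome biogenesis and -0.47 and -1.11 for mature B cell genes. Of all genes tested, 31.6% had groups that did not overlap, where chance gives 2.86%. Leaving out 1 library at a time changed the counts by over 1.5 times without WT_spleen replicate 1 (1425 higher, 896 lower), 3 (1042 lower), 4 (1341 and 810) and 6 (1115 lower) and without Tg_spleen replicate 5 (1470 and 1031). A fit of all 3 groups gave 741 lower genes, and array weights gave 3413.

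Tumours from lymph nodes were compared with wild-type spleen B cells to ask what separates the tumours from normal B cells. The groups also differ in tissue and purification, and these effects are not separated. Myc was at 2020.4 ± 228 against 226 ± 34.7 FPKM (log2 fold change 3.16, adjusted p = 8.04e-05). Among the largest rises were genes of the salivary gland and pancreas. Psp, a parotid secretory protein, was at 2896 ± 2118 against 0.225 ± 0.45 FPKM (log2 fold change 11.74). In WT_spleen it was at 0.9 FPKM in replicate 4 and at 0 in the others, so the size of this fold change depends on the added 0.5 FPKM. Smr3a, another salivary gland gene, was at 389 ± 305 FPKM and was listed at 0 in every WT_spleen library. Then came Chia (357 ± 259.7 against 0.45 ± 0.574 FPKM), Amy1 (736 ± 386 against 2.52 ± 0.984 FPKM), the salivary amylase, Cela2a (650.5 ± 618 against 7.25 ± 8.43 FPKM), a pancreatic elastase, and Dcn (109 ± 11.7 against 0.275 ± 0.32 FPKM), the matrix protein decorin. The largest falls were C6 (0.967 ± 0.208 against 116 ± 17.5 FPKM, log2 fold change -6.31, adjusted p = 6.98e-05), a complement component, Rgs13 (0.767 ± 0.802 against 78.8 ± 34.9 FPKM), Dgki (0.233 ± 0.252 against 36.1 ± 10.2 FPKM) and Lipc (0.4 ± 0.346 against 40.3 ± 9.28 FPKM). Apoc1 (32.5 ± 13.6 FPKM in WT_spleen) and Hs3st2 (23.6 ± 7.02) were listed at 0 in every tumour library. Of 14758 genes tested, 2997 rose and 2619 fell, of which 2028 and 1585 changed at least 2-fold.

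Genes of growth and division rose in the tumours as well. Of nucleolar ribosome biogenesis, 33 of 37 rose and 0 fell (36 and 0 adjusted over the list alone), with Rcl1 (499 ± 54.6 against 159 ± 8.65 FPKM) and Gnl3 (1403 ± 181 against 373 ± 33.7 FPKM), nucleostemin. Of ribosomal proteins, 9 of 35 rose and 0 fell (3 and 0 adjusted over the list alone), of translation factors 13 of 22 rose and 0 fell (14 and 0 adjusted over the list alone), with Eif5a (3043 ± 682 against 959.9 ± 94.7 FPKM), and of aminoacyl-tRNA synthetases 15 of 20 rose and 0 fell (18 and 0 adjusted over the list alone). Of nucleotide and one-carbon synthesis, 26 of 28 rose and 0 fell (26 and 0 adjusted over the list alone), with Tyms (197 ± 32.9 against 20.3 ± 2.09 FPKM). Of polyamine synthesis, 4 of 6 rose and 0 fell (4 and 0 adjusted over the list alone), with Srm (493 ± 70.4 against 96.2 ± 13.8 FPKM). Of glycolysis, 12 of 20 rose and 2 fell (14 and 3 adjusted over the list alone), with Slc16a1 (1066 ± 479 against 73.5 ± 13.7 FPKM). Of oxidative phosphorylation, 20 of 28 rose and 0 fell (20 and 0 adjusted over the list alone), and of protein folding 15 of 16 rose and 0 fell (15 and 0 adjusted over the list alone). Of cholesterol synthesis, 10 of 15 rose and 0 fell (13 and 0 adjusted over the list alone). Of DNA replication, 24 of 28 rose and 0 fell (24 and 0 adjusted over the list alone), with Mcm10 (319 ± 53.9 against 31.6 ± 6.44 FPKM). Of mitosis, 25 of 26 rose and 0 fell (25 and 0 adjusted over the list alone), with Kif23 (369.8 ± 22 against 72.3 ± 6.72 FPKM) and Mki67 (2798 ± 632 against 308 ± 33.9 FPKM), the proliferation antigen Ki-67. Of replication-dependent histones, 15 of 15 rose and 0 fell (15 and 0 adjusted over the list alone). Camera called each of these lists higher (adjusted p = 7.13e-15 to 0.0246). With an estimated correlation none of them passed (adjusted p = 0.197 to 0.542 with an estimated correlation).

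Mature B cell genes were far lower in the tumours. Of that list, 0 of 26 rose and 22 fell (0 and 23 adjusted over the list alone), with Cr2 (80.3 ± 44.1 against 2635 ± 338 FPKM), complement receptor CD21, and Fcer2a (83.1 ± 40.8 against 2248 ± 335 FPKM). The mean log2 level of the list was 8.15 in Tg_lymphnode replicate 3 and 9.58 and 9.54 in the other 2, and its median log2 fold change was -2.47 with replicate 3 and -1.88 without it. Of germinal centre and plasma cell genes, 0 of 12 rose and 6 fell (0 and 7 adjusted over the list alone), with Igj (337 ± 92.8 against 5603 ± 865 FPKM) and Bcl6 (15.3 ± 4.94 against 188 ± 27.9 FPKM). Of immediate early genes, 0 of 11 rose and 7 fell (0 and 7 adjusted over the list alone), with Egr2 (4.7 ± 0.819 against 42.8 ± 7.25 FPKM). In the Bcl2 family list, Bcl2 (69.8 ± 39.7 against 440.1 ± 18 FPKM) and Mcl1 (1125 ± 271 against 3419 ± 371 FPKM), both inhibitors of apoptosis, fell. The list itself did not pass camera, also not without Tg_lymphnode replicate 3 (adjusted p = 0.191). Markers of other cell types differed too. Of collagen and extracellular matrix genes, 18 of 20 rose and 0 fell (18 and 0 adjusted over the list alone), with Col1a2 (119.9 ± 16.3 against 2.65 ± 0.772 FPKM) and Col1a1 (109 ± 22.9 against 1.02 ± 0.574 FPKM), the chains of type I collagen. Of stroma and endothelium markers, 7 of 10 rose and 1 fell (9 and 1 adjusted over the list alone). Of T cell markers, 3 of 13 rose and 0 fell (3 and 0 adjusted over the list alone), with Cd3e (81.5 ± 54.7 against 18.1 ± 4.45 FPKM). Of NK cell markers, 0 of 8 rose and 7 fell (0 and 7 adjusted over the list alone), with Ncr1 (9.7 ± 4.22 against 94.8 ± 24.9 FPKM), and of macrophage and monocyte markers 2 of 12 rose and 7 fell (2 and 7 adjusted over the list alone), with Csf1r (151 ± 27.7 against 834 ± 107 FPKM). Camera gave adjusted p = 1.16e-10 for mature B cell genes, 0.00143 for germinal centre genes, 0.00209 for immediate early genes, 0.0198 for T cell markers, 0.00143 for NK cell markers and 0.0172 for macrophage markers. None of these 6 passed with an estimated correlation (adjusted p = 0.195 to 0.54 with an estimated correlation). Collagen genes passed both ways (adjusted p = 3.01e-11, and adjusted p = 0.0482 with an estimated correlation), but without Tg_lymphnode replicate 3 the second was lost (adjusted p = 0.0889 with an estimated correlation). Stroma markers passed the first only (adjusted p = 2.55e-05, and adjusted p = 0.0915 with an estimated correlation).

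The tumour libraries differed among themselves in genes chosen after their values were seen. Siglech, a gene of plasmacytoid dendritic cells, was at 2655 FPKM in replicate 3. Ctrb1, a pancreatic protease, was at 809, 452 and 2255 FPKM in replicates 1, 2 and 3, and Psp at 735, 2985 and 4968 FPKM. Without replicate 3 the comparison with WT_spleen gave 3466 higher and 3189 lower genes. Interferon-stimulated genes then passed camera (adjusted p = 0.0137, and adjusted p = 0.184 with all 3), as did lysosome genes (adjusted p = 0.0285 and 0.505) and dendritic cell markers (adjusted p = 0.0475 and 0.672). None of these 3 passed with an estimated correlation (adjusted p = 0.601, 0.396 and 0.493 without replicate 3, and 0.853, 0.932 and 0.932 with it). Rpph1 was at 442640 to 608649 FPKM in the tumours, near WT_spleen replicates 1 and 3. Against only those 2 WT_spleen libraries, 1319 genes were higher and 869 lower. Of all genes tested, 45.4% had groups that did not overlap, where chance gives 5.71%.

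**Figure D3:**
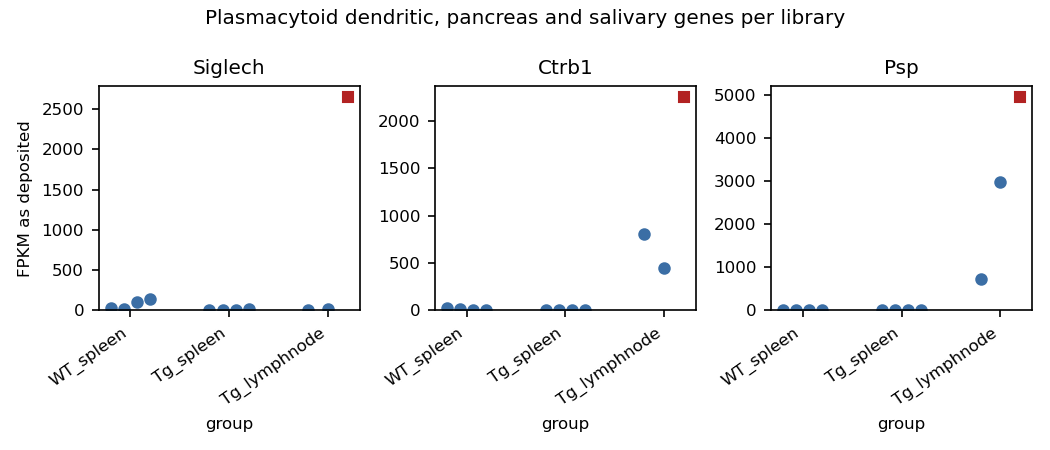
FPKM as deposited (y axis, from 0) of Siglech, Ctrb1 and Psp in each of the 11 B cell and tumour libraries (points) by group (x axis). The square is Tg_lymphnode replicate 3, with 2655 FPKM of Siglech and 4968 FPKM of Psp.

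Tumours were also compared with Tg_spleen to ask what differs between cells that both carry the transgene. These groups also differ in tissue and purification, and these effects are not separated. Myc was at 2020.4 ± 228 against 1556 ± 604 FPKM, with a log2 fold change of 0.45 that did not pass (adjusted p = 0.426). Psp, at 2896 ± 2118 FPKM in the tumours, was listed at 0 in every Tg_spleen library. The next rises were Ctrb1 (1172 ± 955 against 1.35 ± 2.7 FPKM, log2 fold change 9.98, adjusted p = 0.00145), Amy1 (736 ± 386 against 0.5 ± 0.416 FPKM) and Prss2 (679 ± 694 against 0.525 ± 0.64 FPKM), a trypsinogen. The falls were C6 (0.967 ± 0.208 against 104 ± 37.8 FPKM, log2 fold change -6.08, adjusted p = 0.000568) and Dgki (0.233 ± 0.252 against 31.4 ± 8.92 FPKM), and Apoc1 (38.4 ± 22.3 FPKM in Tg_spleen) and Rbm24 (21.5 ± 11.9), listed at 0 in every tumour library. Of collagen and extracellular matrix genes, 17 of 20 rose and 0 fell (19 and 0 adjusted over the list alone), with Tnc (38 ± 12.4 against 0.025 ± 0.05 FPKM), tenascin C, and of stroma and endothelium markers 7 of 10 rose and 0 fell (9 and 0 adjusted over the list alone). Of T cell markers, 4 of 13 rose and 0 fell (11 and 0 adjusted over the list alone), with Cd3e (81.5 ± 54.7 against 9.45 ± 4.74 FPKM, call lost without Tg_lymphnode replicate 2 or Tg_spleen replicate 3 or 5, adjusted p = 0.0527 to 0.0655). Of cholesterol synthesis, 4 of 15 rose and 0 fell (5 and 0 adjusted over the list alone), with Sqle (370.2 ± 23.5 against 164 ± 23.4 FPKM), squalene epoxidase. Of mature B cell genes, 0 of 26 rose and 5 fell (0 and 10 adjusted over the list alone), with Cxcr5 (66.4 ± 40.9 against 933 ± 377 FPKM), the receptor that guides B cells to follicles. Of immediate early genes, 0 of 11 rose and 0 fell (0 and 5 adjusted over the list alone). Camera gave adjusted p = 3.91e-22 for collagen genes, 1.41e-09 for stroma, 1.66e-06 for T cell markers, 7.76e-05 for cholesterol synthesis, 8.06e-09 for mature B cell genes and 0.0051 for immediate early genes. None passed with an estimated correlation (adjusted p = 0.104 to 0.87 with an estimated correlation). Without Tg_lymphnode replicate 3, germinal centre and plasma cell genes (adjusted p = 0.00485), macrophage and monocyte markers (adjusted p = 0.0172) and the Bcl2 family list (adjusted p = 0.0279) were lower by camera and replication-dependent histones higher (adjusted p = 0.00682). With an estimated correlation these 4 did not pass (adjusted p = 0.39 to 0.857 with an estimated correlation).

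Of 14692 genes tested between tumours and Tg_spleen, 523 were higher and 351 lower. The groups did not overlap in 22.4% of all genes tested, where chance gives 5.71%. Quantile normalization gave 364 higher and 369 lower genes. Leaving out Tg_spleen replicate 2 gave 277 and 119, replicate 3 gave 204 and 93, and replicate 5 gave 274 and 126. Leaving out Tg_lymphnode replicate 2 gave 306 and 211. The 2 Tg_spleen libraries with high Rpph1 against the tumours gave 145 higher and 107 lower genes, and a fit of all 3 groups gave 1056 and 1071.

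In the fibroblasts, MycER was activated for 4 h to ask which genes respond early. The 0 h libraries had no 4-hydroxytamoxifen, and there were no untreated later times and no cells without MycER. Effects of MycER, of the compound itself and of time are therefore not separated at 4, 8 and 16 h, nor in nascent RNA. The listed Myc transcript fell, with 10.8 ± 2.84 against 24.3 ± 3.98 FPKM (log2 fold change -1.15, adjusted p = 0.000875). The largest rises were Rgcc (41.4 ± 1.14 against 4.53 ± 0.337 FPKM, log2 fold change 3.06, adjusted p = 1.84e-11), a regulator of the cell cycle, and Slc38a3 (5.68 ± 3.1 against 0.29 ± 0.0818 FPKM, log2 fold change 2.80, adjusted p = 1.89e-05), a glutamine transporter. Then came Ankrd6 (12.9 ± 4.71 against 1.74 ± 0.269 FPKM), Cited1 (15.5 ± 8.24 against 2.4 ± 0.491 FPKM), Reep6 (20.6 ± 6.29 against 4.75 ± 1.04 FPKM) and Nrtn (7.29 ± 2.77 against 1.69 ± 0.864 FPKM), the growth factor neurturin. The largest falls were Foxs1 (1.78 ± 0.883 against 10.1 ± 0.882 FPKM, log2 fold change -2.28, adjusted p = 8.33e-05) and Angptl4 (1.67 ± 0.946 against 8.73 ± 1.75 FPKM, log2 fold change -2.16, adjusted p = 2.8e-05), an inhibitor of lipoprotein lipase. Then came Gvin1 (4.81 ± 4.28 against 17.7 ± 1.59 FPKM), Asb5 (1.37 ± 1.25 against 5.36 ± 2.28 FPKM), Htr2a (3.23 ± 1.69 against 11.3 ± 3.17 FPKM), a serotonin receptor, and Tmem171 (11.2 ± 4.22 against 36 ± 4.25 FPKM). Of 12934 genes tested, 246 rose and 372 fell, of which 83 and 140 changed at least 2-fold. Of immediate early genes, 0 of 11 rose and 3 fell (0 and 5 adjusted over the list alone), with Dusp1 (23.9 ± 2.49 against 48.5 ± 6 FPKM), a phosphatase of MAP kinases. Of actin cytoskeleton and YAP or SRF targets, 0 of 16 rose and 3 fell (0 and 5 adjusted over the list alone), with Ankrd1 (19.5 ± 7.28 against 53.5 ± 6.77 FPKM). Of cholesterol synthesis, 2 of 16 rose and 0 fell (3 and 0 adjusted over the list alone), with Dhcr7 (36.3 ± 8.39 against 20.6 ± 3.31 FPKM, call lost without OHT_0h replicate 1 or 4 or OHT_4h replicate 1, 2 or 3, adjusted p = 0.0559 to 0.0923). Of nucleolar ribosome biogenesis, 1 of 37 rose and 0 fell (0 and 0 adjusted over the list alone), namely Rrp9 (107 ± 19.3 against 79.7 ± 3.57 FPKM, call lost without OHT_0h replicate 1, 2, 3 or 4 or OHT_4h replicate 1 or 3, adjusted p = 0.0643 to 0.125), with a median log2 fold change of 0.11. Of stroma and endothelium markers, 0 of 7 rose and 1 fell (0 and 2 adjusted over the list alone), and of germinal centre and plasma cell genes 0 of 8 rose and 2 fell (0 and 2 adjusted over the list alone), which were Xbp1 (24.5 ± 4.41 against 35.5 ± 0.889 FPKM, call lost without OHT_0h replicate 1, 2 or 3 or OHT_4h replicate 1, 2 or 3, adjusted p = 0.0611 to 0.0969), a regulator of the unfolded protein response, and Fas (4.79 ± 1.25 against 9.17 ± 1.69 FPKM, call lost without OHT_0h replicate 2, 3 or 4 or OHT_4h replicate 1, 2 or 3, adjusted p = 0.0599 to 0.118), a death receptor. Camera gave adjusted p = 0.000176, 9.95e-06, 0.000176, 0.000479, 0.0166 and 0.0374 for these 6 lists in that order. The last was lost with median ratio scaling (adjusted p = 0.0511, in a range of 0.0103 to 0.0586 over its alternatives). None of the 6 passed with an estimated correlation (adjusted p = 0.473 to 0.685 with an estimated correlation).

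**Figure D4:**
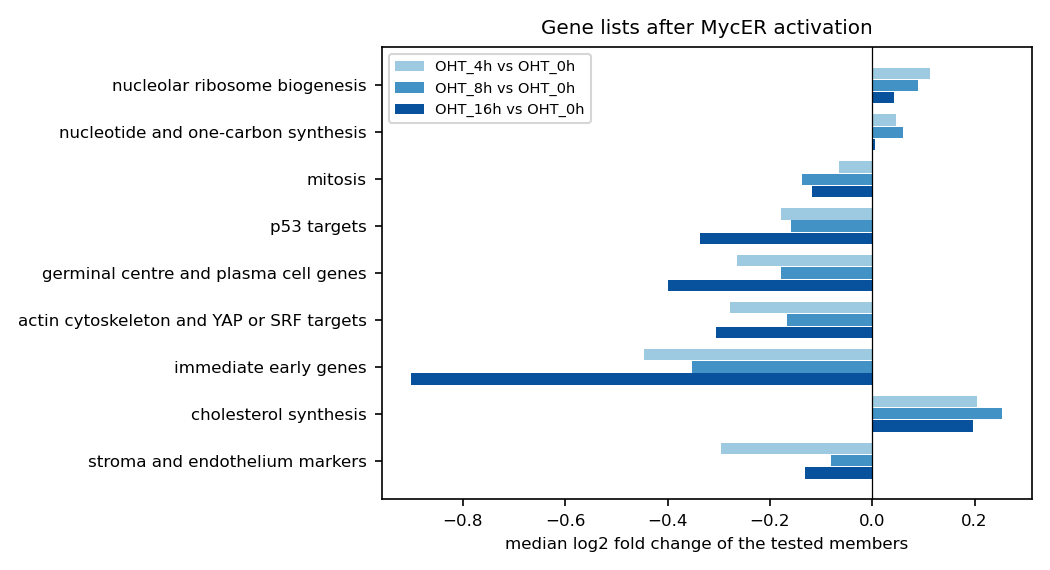
Median log2 fold change of the tested members of each gene list (x axis) at 4, 8 and 16 h against 0 h (bars), for lists that passed camera at any time (y axis). Immediate early genes had medians of -0.45, -0.35 and -0.90, and cholesterol synthesis 0.20, 0.25 and 0.20.

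At 4 h, groups did not overlap in 12.5% of all genes tested, where chance gives 2.86%. Leaving out 1 library changed a count by over 1.5 times for OHT_0h replicates 1 (161 higher, 218 lower), 2 (180 lower), 3 (225 lower) and 4 (212 lower). The same held for OHT_4h replicates 1 (118 lower), 2 (145 and 120) and 3 (145 higher). Median ratio scaling gave 660 higher and 816 lower genes, quantile normalization 858 and 905, and array weights 812 and 1735. A fit of the 2 groups alone gave 794 lower genes. The 4 libraries numbered 4 listed 1051, 1320, 1861 and 1943 genes at 0 FPKM at 0, 4, 8 and 16 h, against 519 to 1173 in the other 12. Without those 4 libraries, 411 genes were higher and 865 lower. Values of abundant genes in the fibroblast libraries lay close together, with the top 0.1% of genes starting at 113 to 128 FPKM and Actb, cytoskeletal actin, at 119 FPKM in OHT_0h. Log2 fold changes at 4 h had an SD of 0.35 among genes under 50 FPKM and 0.16 among genes of 50 FPKM or more, and 590 of 11148 and 28 of 1786 were called. No data without such a flat top were set beside this contrast, so it does not show by itself that fold changes were narrowed. If the values of abundant genes are limited, their changes, and those of lists that hold them, may be missed at 4, 8 and 16 h.

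At 8 h, 156 genes rose and 127 fell. Myc was at 12.5 ± 2.2 against 24.3 ± 3.98 FPKM (log2 fold change -0.94, adjusted p = 0.00811). The largest rises were Rgcc (40.3 ± 9.66 against 4.53 ± 0.337 FPKM, log2 fold change 2.99, adjusted p = 2.78e-11), Ankrd6 (10.8 ± 1.51 against 1.74 ± 0.269 FPKM) and Fzd9 (19.7 ± 1.77 against 5.02 ± 0.456 FPKM), a Wnt receptor, then Adora2b (7.83 ± 1.87 against 1.84 ± 0.334 FPKM) and P2ry2 (7.39 ± 0.541 against 1.77 ± 0.327 FPKM), receptors for adenosine and for nucleotides, and Reep6 (17 ± 3.97 against 4.75 ± 1.04 FPKM). The largest falls were Ccng2 (8.72 ± 2.68 against 30 ± 2 FPKM, log2 fold change -1.78, adjusted p = 0.000787), a cyclin of quiescent cells, and Foxs1 (2.77 ± 1.15 against 10.1 ± 0.882 FPKM), followed by Fam214b (1.86 ± 0.78 against 6.36 ± 0.733 FPKM), Angptl4 (2.58 ± 0.733 against 8.73 ± 1.75 FPKM), Arntl (3.09 ± 1.13 against 9.38 ± 1.48 FPKM), the clock factor Bmal1, and Stx11 (3.33 ± 0.504 against 9.57 ± 1.59 FPKM). Of immediate early genes, 0 of 11 rose and 3 fell (0 and 5 adjusted over the list alone), with Dusp1 (21.4 ± 4.02 against 48.5 ± 6 FPKM) and Ier3 (40.3 ± 7.39 against 66.5 ± 9.25 FPKM). Of cholesterol synthesis, 0 of 16 rose and 0 fell (7 and 0 adjusted over the list alone). Of mitosis, 0 of 26 rose and 1 fell (0 and 1 adjusted over the list alone), with Nusap1 (31.8 ± 4.57 against 51.1 ± 4.15 FPKM, call lost without OHT_0h replicate 2, adjusted p = 0.0644). Of actin cytoskeleton and YAP or SRF targets, 0 of 16 rose and 1 fell (0 and 1 adjusted over the list alone), with Ankrd1 (26.4 ± 4.47 against 53.5 ± 6.77 FPKM, call lost without OHT_0h replicate 2, adjusted p = 0.0569). Of nucleolar ribosome biogenesis, 0 of 37 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.09. Camera gave adjusted p = 9.01e-05, 1.27e-06, 0.00523, 0.00518 and 0.000324 in that order, and none passed with an estimated correlation (adjusted p = 0.539 to 0.943 with an estimated correlation). Groups did not overlap in 13% of all genes tested, where chance gives 2.86%. Every library left out moved a count by over 1.5 times. Leaving out OHT_0h replicates 1 to 4 gave 95 and 59, 107 and 48, 97 and 68, and 90 and 57 higher and lower genes. Leaving out OHT_8h replicates 1 to 4 gave 93 and 96, 95 and 62, 93 and 73, and 164 and 66. Median ratio scaling gave 552 and 440, quantile normalization 675 and 490, and array weights 1074 and 751. A fit of the 2 groups alone gave 225 higher and 284 lower genes.

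At 16 h, 228 genes rose and 1002 fell. Myc was at 9.78 ± 1.41 against 24.3 ± 3.98 FPKM (log2 fold change -1.27, adjusted p = 0.000239). The largest rises were Rgcc (44.9 ± 5.01 against 4.53 ± 0.337 FPKM, log2 fold change 3.17, adjusted p = 9.04e-12), Ankrd6 (12.4 ± 2.17 against 1.74 ± 0.269 FPKM), Ppm1j (5.27 ± 1.29 against 0.658 ± 0.113 FPKM), Cited1 (11.2 ± 3.38 against 2.4 ± 0.491 FPKM), Nrtn (7.58 ± 3.25 against 1.69 ± 0.864 FPKM) and Fzd9 (20.6 ± 6.89 against 5.02 ± 0.456 FPKM). The largest falls were Foxs1 (1.48 ± 0.67 against 10.1 ± 0.882 FPKM, log2 fold change -2.48, adjusted p = 3.26e-05), Angptl4 (1.39 ± 0.298 against 8.73 ± 1.75 FPKM), Gvin1 (4.12 ± 1.91 against 17.7 ± 1.59 FPKM), Tmem171 (8.77 ± 2.06 against 36 ± 4.25 FPKM), Sema7a (1.59 ± 0.305 against 8.03 ± 3.09 FPKM) and Arntl (2.19 ± 0.821 against 9.38 ± 1.48 FPKM). Of immediate early genes, 0 of 11 rose and 7 fell (0 and 9 adjusted over the list alone), with Ier3 (30 ± 4.63 against 66.5 ± 9.25 FPKM), Dusp1 (19.6 ± 5.3 against 48.5 ± 6 FPKM) and Fos (1.66 ± 0.156 against 4.94 ± 1.37 FPKM). Of p53 targets, 0 of 18 rose and 5 fell (0 and 6 adjusted over the list alone), with Btg2 (3.33 ± 0.739 against 12.5 ± 1.14 FPKM), an inhibitor of proliferation, and Eda2r (1.45 ± 0.65 against 4.02 ± 1.48 FPKM). Of actin cytoskeleton and YAP or SRF targets, 0 of 16 rose and 3 fell (0 and 12 adjusted over the list alone), with Ankrd1 (17.6 ± 4.38 against 53.5 ± 6.77 FPKM) and Ctgf (43 ± 4.22 against 74.7 ± 5.85 FPKM). Of cholesterol synthesis, 0 of 16 rose and 0 fell (3 and 0 adjusted over the list alone). Of nucleolar ribosome biogenesis, 0 of 37 rose and 0 fell (0 and 0 adjusted over the list alone), and of nucleotide and one-carbon synthesis 0 of 28 rose and 0 fell (0 and 0 adjusted over the list alone), with medians of 0.04 and 0.01 (0.20 and 0.16 with median ratio scaling). Camera gave adjusted p = 7.41e-07, 0.0476, 8.64e-05, 3.76e-06, 0.000272 and 0.0391 in that order. None passed with an estimated correlation (adjusted p = 0.403 to 0.746 with an estimated correlation). Without the libraries numbered 4, p53 targets (adjusted p = 0.116, range over alternatives 0.0454 to 0.116) and nucleotide synthesis (adjusted p = 0.155, range 0.00219 to 0.155) no longer passed. With median ratio scaling, ribosomal proteins (adjusted p = 0.0128), translation factors (adjusted p = 0.00784) and protein folding (adjusted p = 0.0444) passed as well, but not with an estimated correlation (adjusted p = 0.533 for each). Their members Rplp0, Eef1a1 and Hsp90ab1 were at 117, 124 and 117 FPKM in OHT_0h, where values of abundant genes lie close together. Genes held near 1 level would seem to rise once a downward shift of all genes is scaled out. These 3 calls cannot be told from that limit.

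The median log2 fold change of all genes at 16 h was -0.14 against 0 h and -0.11 against 4 h on the deposited scale. Median ratio scaling, which removes this shift, gave 831 higher and 1095 lower genes, and quantile normalization 999 and 1053. The share of calls that were higher was 18.5% as deposited, 43.1% with median ratio scaling and 48.7% with quantile normalization. Without OHT_0h replicate 1 or 2, 663 or 560 genes fell. Without OHT_16h replicate 1, 1886 fell, without replicate 2, 448, and without replicate 4, 496. Without the libraries numbered 4 and OHT_16h replicate 2, 883 genes rose and 613 fell. Groups did not overlap in 13.8% of all genes tested, where chance gives 2.86%.

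From 4 h to 16 h, limma called 0 genes higher and 0 lower, with 218 genes at an unadjusted p under 0.05. Myc was at 9.78 ± 1.41 against 10.8 ± 2.84 FPKM. In all, 3 lists passed camera. Immediate early genes were lower, with a median log2 fold change of -0.31 and 3 members adjusted over the list alone (adjusted p = 8.21e-07, and adjusted p = 0.41 with an estimated correlation). Ier3 was at 30 ± 4.63 against 45.4 ± 4.08 FPKM. Ribosomal proteins were higher relative to other genes (adjusted p = 0.0271, and adjusted p = 0.473 with an estimated correlation), although their median was -0.01 (0.10 with median ratio scaling), and without the libraries numbered 4 the call was lost (adjusted p = 0.306, range over alternatives 0.000567 to 0.306). Stroma and endothelium markers were also higher in this sense (median 0.04, adjusted p = 0.0186, and adjusted p = 0.473 with an estimated correlation). With median ratio scaling another 11 lists passed, among them protein folding (adjusted p = 0.00868), nucleotide and one-carbon synthesis (adjusted p = 0.0132), translation factors (adjusted p = 0.0172) and nucleolar ribosome biogenesis (adjusted p = 0.0436). None of the 11 passed with an estimated correlation (adjusted p = 0.308 to 0.545 with an estimated correlation). Members such as Rplp0 and Eef1a1, at 117 and 124 FPKM in OHT_0h, lie where values of abundant genes are close together. Genes held near 1 level would stay in place while all genes shift down. Higher calls for lists of abundant genes cannot be told from that limit. Without the libraries numbered 4, germinal centre and plasma cell genes (adjusted p = 0.0096), cholesterol synthesis (adjusted p = 0.0096) and actin cytoskeleton and YAP or SRF targets (adjusted p = 0.0258) passed as higher, but not with an estimated correlation (adjusted p = 0.884 for each). Of all genes tested, 0.387% had groups that did not overlap, where chance gives 2.86%.

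Nascent RNA at 4 h was set beside 0 h to ask which genes change in new transcription. There is 1 library per time, so values carry no error and no test. Among 12375 genes with at least 1 FPKM in either library, the median log2 ratio was 0.02, with 147 genes at least 2-fold higher and 87 at least 2-fold lower. Rgcc was at 8.79 against 0.589 FPKM (log2 ratio 3.09), Gtdc2 at 10.01 against 1.91 (2.12) and Fzd9 at 5.77 against 1.07 (2.00). Reep6 (1.98), Il15ra (1.94) and Dusp2 (1.88) came next. The lowest log2 ratios were those of Apol8 (-2.29), Arntl (-1.74), Ccng2 (-1.70), Tgfb1i1 (-1.54), Leap2 (-1.53) and Kcnk7 (-1.49). Myc was at 25.2 FPKM at 4 h against 33.1 at 0 h. Of the genes called higher in total RNA at 4 h and measured here, 222 of 223 were higher in nascent RNA (median log2 ratio 0.90), and of those called lower, 306 of 321 were lower (median -0.51). Across 12155 genes, which are not independent replicates, the nascent and total log2 values had r = 0.665 and rho = 0.621. In nascent RNA, cholesterol synthesis had a median log2 ratio of 0.53, replication-dependent histones 0.37 and nucleolar ribosome biogenesis 0.18, at percentiles 100, 100 and 99.98 of 10000 random lists of like level. The medians of mitosis (-0.17), actin cytoskeleton and YAP or SRF targets (-0.17) and collagen genes (-0.09) lay at percentiles 0, 0 and 0.05. Immediate early genes, lower in total RNA at 4 h, were not lower in nascent RNA (median 0.07, 7 of 12 higher, percentile 66.3).

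Calls in B cells and fibroblasts were set against each other to ask whether the same genes move in both systems. Of genes tested in both fits, 56 rose both in Tg_spleen and at 4 h (36.4 expected), and 63 fell in both (27.8 expected). Fisher's exact test, two-sided, gave adjusted p = 0.00138 and 1.33e-09 over 18 tests. At 16 h, 221 genes fell in both against 83.2 expected (adjusted p = 1.72e-45), and 45 rose in both against 33 expected (adjusted p = 0.0285). For 8 h and Tg_spleen, 30 rose in both against 22.96 expected, which did not pass (adjusted p = 0.105), and 22 fell in both against 10.2 expected (adjusted p = 0.00138). Among changes of at least 2-fold, rises shared with Tg_spleen did not pass at 4 h (6 against 4.46 expected, adjusted p = 0.479) or at 16 h (7 against 4.15, adjusted p = 0.238), while shared falls did (10 against 2.58, adjusted p = 0.00109, and 30 against 5.90, adjusted p = 2.22e-12). In the tumours, 280 genes fell with 16 h against 141 expected (adjusted p = 2.95e-33), and 63 rose with 4 h against 45.1 expected (adjusted p = 0.00604). At 2-fold, rises shared with the tumours passed at 4 h (15 against 8.20 expected, adjusted p = 0.0421), 8 h (14 against 6.81, adjusted p = 0.0159) and 16 h (16 against 7.65, adjusted p = 0.00845). Falls shared with the tumours passed at 4 h (20 against 9.41, adjusted p = 0.00544) and 16 h (56 against 19.6, adjusted p = 2.22e-12). They did not at 8 h (7 against 3.08, adjusted p = 0.0545). Genes moving in opposite directions were counted without a test. Of genes higher in Tg_spleen than in WT_spleen, 17 fell at 4 h (45.9 expected) and 47 at 16 h (137 expected). Of those higher in tumours than in WT_spleen, 30 and 86 fell (63.7 and 181 expected). Of those higher in tumours than in Tg_spleen, 20 and 42 fell (7.37 and 21.3 expected), while 10 and 12 rose (5.42 and 4.95 expected). Genes are not independent replicates, and the expected counts take each gene as equally likely to be called. At 4 h, 5.29% of fibroblast genes under 50 FPKM were called and 1.57% of those of 50 FPKM or more. This may shift the balance of shared rises and falls. Only calls of the main fit were used, where 228 genes rose and 1002 fell at 16 h. Without the libraries numbered 4 and OHT_16h replicate 2, 883 rose and 613 fell. Against WT_spleen, 1568 genes rose and 1105 fell in both Tg_spleen and the tumours, where 413 and 321 are expected. A shared control can add to such counts. With the controls split 2 and 2 in 6 ways, a mean of 179 rose and 30.3 fell in both, where 22.1 and 5.48 are expected, but single splits gave 26 to 458 rises and 1 to 86 falls. In fibroblasts, 188 genes rose and 359 fell both at 4 h and at 16 h, where 4.34 and 28.8 are expected. With these controls split, a mean of 69.5 rose and 62.8 fell in both (63 to 73 and 49 to 86), where 0.802 and 2.31 are expected.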

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

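Every test weighed here was chosen only after the result was seen, except those of lists for plasmacytoid dendritic cells and for the pancreas, whose genes had not been looked at. In groups of 4 libraries, a single library far from the other 3 (its gap to the nearest above Dixon's 95% limit) was found in 22 of 309 sets of values tested. Chance flags about 1 in 20 groups, or 15.45 sets here.

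Among WT_spleen libraries, replicate 3 had a median of 14.5 FPKM over all genes (lowest other 13.3), replicate 6 a mean log2 level of T cell markers of 5.41 (others 4.50 to 4.57) and 4.0 FPKM of Amy1 (others 2.0 to 2.1), and replicate 4 had 0.9 FPKM of Psp (others 0). Replicate 6 also had 22.1 FPKM of Kit (others 13.1 to 14.1). Among Tg_spleen libraries, replicate 5 had 5.4 FPKM of Ctrb1 (others 0) and replicate 4 had 0.1 FPKM of Tnc (others 0) and 37.6 FPKM of Cdkn2a (others 8.9 to 10.9).

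Among fibroblasts, OHT_0h replicate 1 had a mean log2 level of 5.96 for actin cytoskeleton and YAP or SRF targets (others 6.00 to 6.01), and OHT_0h replicate 3 one of 3.82 for immediate early genes (others 4.01 to 4.04). OHT_8h replicate 2 had 115 FPKM of Rmrp (others 93.03 to 95.2). In replicate 4, 11 values stood apart. They were Eda2r (6.21 FPKM, others 3.11 to 3.61) and Htr2a (16.1, others 9.32 to 10.2) at 0 h, Asb5 (3.23, others 0.643 to 0.917), Gvin1 (11.2, others 2.12 to 2.99), Htr2a (5.73, others 2.14 to 2.74) and Xbp1 (31.1, others 21.9 to 22.9) at 4 h, Arntl (1.41, others 3.50 to 3.79) and Nusap1 (24.97, others 33.8 to 34.5) at 8 h, with mean log2 levels at 8 h of 5.57 for actin cytoskeleton and YAP or SRF targets (others 5.81 to 5.86) and 5.33 for mitosis (others 5.54 to 5.58), and Rpph1 at 16 h (104 FPKM, others 82.96 to 86.2).

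Abundant genes in the fibroblast files lie near a single level. In OHT_0h, Actb was at 119, Gapdh at 132 and Eef1a1 at 124 FPKM, while Actb was at 32816 FPKM in WT_spleen. The top 0.1% of genes started at 113 to 128 FPKM in the 16 total RNA libraries and 66.5 FPKM in 4sU_0h. A fixed limit in FPKM would give the same value in each file, and 66.5 FPKM argues against it. A true common level of abundant genes in total RNA stays open, since the denominators of the 16 total RNA libraries lie so close (their lowest is 16.97 and their highest 17.06, in units of 1e6 reads) that the slope of this level on them, on log scales, was 3.57 ± 4.87 (standard error). Removal of duplicate reads, which allows a fixed number of reads per base, also stays open. With the denominators that the lowest values give, that limit was 1.85 reads per base in 4sU_0h, 1.71 in 4sU_4h and 1.93 to 2.19 in total RNA, against 9.30 to 25.2 in the B cell files. Removal of duplicates may therefore have narrowed fold changes of abundant genes in fibroblasts. No biological explanation was tested.

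Tg_lymphnode replicate 3 held 1.54% of the level of the other 2 tumours for Ebf1 and 8.20% for Pax5, transcription factors of B cells, with Cd4 at 9468 FPKM and Siglech at 2655 FPKM. An exchange with a spleen library was argued against by its collagen and extracellular matrix list, with a mean log2 level of 5.22 where the 8 spleen libraries lay at 0.66 to 1.5. T cells as the origin of Cd4 were argued against by Cd3e at 62.8 FPKM, between 38.6 and 143 FPKM in the other 2 tumours. For cells like plasmacytoid dendritic cells, 3 of 10 listed genes lay over 4 times above the highest of the other 10 libraries (Cox6a2 at 1305, Lair1 at 723 and Paqr5 at 69.5 FPKM). This count, with 5 needed by the bound set beforehand and under 3 to argue against, leaves such cells open. The most abundant listed gene was Pld4, at 2233 FPKM and 1261 FPKM in the highest other library. It and others are thus also seen in the bead-enriched spleen libraries, and which cells there hold them was not tested. A tumour of another cell type remains possible and was not tested.

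The 3 tumour suspensions held RNA of pancreas and salivary gland genes. Of 7 pancreas genes not looked at before, 6 were higher in each tumour than in every spleen library (not Spink3), as pancreas carried along with the lymph nodes, or pancreas RNA of another origin, would give, so the origin stays open. Among 16 such genes seen before, the highest in a tumour was Ctrb1 at 2255 FPKM. Reads from 1 outside library were argued against by the ratio of Psp to Ctrb1, which was 0.909, 6.60 and 2.20 in the 3 tumours, a spread of 7.26 times. Of the bead-enriched spleen libraries, WT_spleen replicates 1 and 3 held Ctrb1 at 28.6 and 18.9 FPKM and the other 6 at 0 to 5.4 FPKM, where the lowest tumour had 452 FPKM. WT_spleen replicates 1 and 3 had Psp at 0, and why they held Ctrb1 stays open. No biological explanation was tested.

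Other splits of the same libraries into groups of the same sizes, 35 per comparison, were tested in the same way. Only 1 of the 35, the real one, gave as many calls in Tg_spleen vs WT_spleen (3918, highest other 27), Tg_lymphnode vs WT_spleen (5616, highest other 4), Tg_lymphnode vs Tg_spleen (874, highest other 5), OHT_4h vs OHT_0h (618, highest other 1), OHT_8h vs OHT_0h (283, highest other 1) and OHT_16h vs OHT_0h (1230, highest other 1). With 35 splits, the real one can be no rarer than 1 in 35, and these comparisons share groups. The other splits mix libraries of both groups, so a real difference widens their spread and lowers their calls. The low counts of the other splits therefore do not exclude chance. The split with 27 calls parts the libraries by Rpph1 level. For OHT_16h vs OHT_4h, 0 calls were found, which 35 of 35 splits reach by necessity, so their number says nothing about chance. Another split of those 8 libraries set replicates 1 and 4 at 4 h and 2 and 4 at 16 h against the rest. It gave 1110 calls, which points to a structure of the samples. The median over all genes was 2.942, 2.885, 2.529 and 2.114 FPKM in these replicates and 3.227 to 3.962 FPKM in the rest. The split thus parts the libraries by their level on the deposited scale. Whether that level gave the calls was not tested.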

How the results depend on the processing

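Tests chosen only after the data were seen are those by Rpph1 level, without libraries numbered 4, with a filter of 10 and pseudocount 5, with genes under 50 FPKM, and list tests without Tg_lymphnode replicate 3, by library batch, or with an estimated correlation under another setting. Across 696 results and 53 settings, counts of calls were within 1.5 times in 192 alternative values, and 96 moved further. Of values for single genes and lists, 3133 kept their direction and side of the threshold, 392 fell short of it, 38 newly passed and 108 moved. For Tg_lymphnode vs WT_spleen, no count moved by over 1.5 times on leaving out a library.

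Where a count moved, the cause was not tested. For Tg_spleen vs WT_spleen, array weights gave 3413 lower genes, all groups in 1 fit 741 lower, and only libraries with high Rpph1 908 higher and 518 lower. For Tg_lymphnode vs WT_spleen, high Rpph1 gave 1319 and 869. For Tg_lymphnode vs Tg_spleen, a filter of 5 gave 324 higher, a filter of 10 with pseudocount 5 gave 251 higher, array weights 1215 and 1145, all groups in 1 fit 1056 and 1071, and high Rpph1 145 and 107.

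At 4 h, median ratio scaling gave 660 higher and 816 lower, quantile normalization 858 and 905, array weights 812 and 1735, only the 2 groups 794 lower, no libraries numbered 4 gave 411 and 865, and also no OHT_16h replicate 2 gave 722 and 1385. At 8 h the values were 552 and 440, 675 and 490, 1074 and 751, 284 lower, 262 higher, and 572 and 460. At 16 h, median ratio scaling gave 831 higher, quantile normalization 999, array weights 507, and no libraries numbered 4 and no OHT_16h replicate 2 gave 883 and 613. For OHT_16h vs OHT_4h, no libraries numbered 4 gave 2 lower, and also no OHT_16h replicate 2 gave 36 higher and 5 lower. Genes under 50 FPKM gave 242 and 371 at 4 h, 162 and 140 at 8 h and 219 and 988 at 16 h.

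Leaving out 1 library gave 1341 to 2684 higher and 810 to 2400 lower for Tg_spleen vs WT_spleen, 204 to 506 and 93 to 414 for Tg_lymphnode vs Tg_spleen, 145 to 285 and 118 to 488 at 4 h, 90 to 164 and 48 to 96 at 8 h, and 155 to 229 and 448 to 1886 at 16 h.

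With a replicate block (samples of the same number paired), limma gave 0 higher and 0 lower for Tg_spleen vs WT_spleen, with 3366 genes at an unadjusted p under 0.05 and 3 residual degrees of freedom, Tg_lymphnode vs Tg_spleen 174 and 153, 4 h 408 and 697, 8 h 313 and 416, and 16 h 349 and 1722. The cause was not tested. Same numbers were not taken as pairs, since no label gives them a shared day or batch. Of the 9 B cell libraries whose number another group shares, 3 correlated best with their own number, as did 8 of 16 fibroblast libraries. All 24 same-number fibroblast pairs were positive, down to 0.0131. Libraries numbered 4 correlated at 0.317 to 0.640 with each other and at -0.522 to 0.0467 with other numbers. Fibroblast libraries numbered 4 thus share an effect that the main fit does not take out. With the block, more genes were called than in the main fit at 4, 8 and 16 h. With the block, p53 targets at 16 h (adjusted p = 0.0682) and germinal centre and plasma cell genes at 4 h (adjusted p = 0.0586) no longer passed camera, and 9 lists newly passed. They were immediate early genes for Tg_spleen vs WT_spleen (adjusted p = 0.0133), interferon-stimulated genes for Tg_lymphnode vs WT_spleen (0.00115), nucleolar ribosome biogenesis, nucleotide synthesis, mitosis, germinal centre genes and macrophage markers for Tg_lymphnode vs Tg_spleen (0.0217 to 0.0417), and nucleotide synthesis and the Bcl2 family at 8 h (0.0484 and 0.0432). None of the 9 passed with an estimated correlation (adjusted p = 0.402 to 0.952).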

Other observations

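The lists not described for Tg_spleen vs WT_spleen did not pass camera (adjusted p over 0.05). With the library batch by Rpph1 as a covariate, immediate early genes (adjusted p = 0.0169) and macrophage markers (adjusted p = 0.0182) passed, but not with an estimated correlation (adjusted p = 0.423 and 0.561). B cell progenitor genes had 4 of 15 higher and 2 lower, with a median log2 difference of -0.24 in libraries with high Rpph1 and 2.04 in those with low Rpph1. Myc and its network had 4 of 12 higher and 1 lower, and Bcl2 family and Arf 3 of 12 higher and 1 lower. Immediate early genes had 0 of 11 higher and 2 lower, and lysosome genes 1 of 20 higher and 3 lower. In nascent RNA, nucleotide and one-carbon synthesis was higher for 25 of 28 genes (median log2 ratio 0.13) and polyamine synthesis for 7 of 7 (0.20). Both medians lay inside the 95% range of random lists of like level (upper limits 0.134 and 0.210, percentiles 96.9 and 97.2). Other pseudocounts of 0.1 and 1 gave 225 and 95 genes at least 2-fold higher and 137 and 55 at least 2-fold lower in nascent RNA.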
